A study of Mus musculus with 2 samples.

How the data were processed

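Polyadenylated RNA from primary regulatory T cells of a male adult mouse aged 9 weeks was sequenced, per the labels, as 2 technical replicate libraries of biological replicate 1. Regulatory T cells are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. The strain name in the labels carries alleles at Foxp3 (a GFP and diphtheria toxin receptor reporter), at CD4 (a tamoxifen-inducible Cre) and at the R26 locus (tdTomato). The labels gave a sheared preparation and did not state how the cells were purified. There was 1 group, so no conditions could be compared. The labels did not say whether the libraries began from the same RNA or from separately handled cells. Every p-value below therefore measures only the counting error between these 2 libraries and has no replicate check. Grouping followed the labels alone.

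The authors deposited, for each library, a gene table and a transcript table made on the mouse genome build mm10 with the GENCODE M21 annotation, per the text descriptions deposited beside them. The column headings were those that RSEM writes, while the aligner, the quantifier and their versions were not given in the sources used here. The expected counts deposited by the authors are estimated reads per gene, which need not be whole because reads shared between genes are divided. The TPM values deposited by the authors (transcript abundance scaled to a fixed total) and the deposited FPKM values (fragments scaled by transcript length and depth) were already scaled for transcript length and depth. The authors also deposited posterior mean counts, and a signal of posterior mean TPM with 95% credibility bounds, per the file headers. The deposited coefficients of quartile variation, which are fractions, were not used here. These bounds belong to the posterior mean and need not contain the TPM: for Foxp3 in technical replicate 1 the TPM was 88.6 and the bounds were 76.4 and 84.5. The percent of each gene taken by each of its transcripts was also a deposited value, per the file headers. Effective length was shorter than length by 49 bases in 100% of transcripts over 100 bases. A further gene table per library, deposited as whole-number counts on the older GENCODE M4 annotation, held 22457 genes, of which 22195 matched a gene of the newer table and 21352 of those were protein coding. The tool that made those counts was not given in the sources used here. The deposited text descriptions were read for the build and annotation and hold no measurement.

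Each newer gene table held 81881 rows, of which 55536 named a gene. The rest were 26248 rows with numeric identifiers, 96 rows of ERCC spike-in RNA and a row of the phage phiX174. Rows that named no gene stayed out of library sizes and tests. The numeric rows held 0.00930% of counts in technical replicate 1 and 0.00806% in technical replicate 2, the phiX174 row held 0.298% and 0.234%, and the ERCC rows held 0. Expected counts were rounded to whole numbers for tests. Gene counts summed to 20891069 and 18571065, and the older tables summed to 6047614 and 5889818. At these depths 3 counts corresponded to 0.131 TPM of Foxp3 in technical replicate 1 and 0.157 TPM in technical replicate 2. Confidence intervals of shares were 95% exact binomial intervals. They and the floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

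A gene was called detected at a TPM of at least 1 in both libraries. The libraries were compared per gene with a two-sided exact binomial test, conditional on the gene's total, among genes with at least 10 counts over both. The expected share came from library sizes scaled with edgeR's TMM, whose factors were 1.02 and 0.978, and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. edgeR's quasi-likelihood test could not be fitted, as the design left no residual degrees of freedom. Log2 ratios are technical replicate 2 over technical replicate 1, with 0.5 added to each count, and their standard error is the counting error. Means ± SD are over the 2 technical libraries (n = 2). The spread between libraries was measured as the Pearson chi-square per degree of freedom, which is about 1 under sampling noise alone. For each list of genes, the median log2 ratio of TPM + 1 over members with at least 10 counts was placed among 10000 random lists matched on mean TPM from the nearest 50 genes. Such a percentile describes these libraries and is not a p-value. The reads behind the 2 gene tables were compared by Spearman's rho across genes, and genes are not independent replicates.

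The 31 lists (19 of gene programmes and 12 of markers of other cell types), the tests and most alternative settings were set before the data were examined. Named genes followed a rule set at the same time: any member of the Treg identity list, the 4 members with the highest mean TPM of every other list or all members of a list of under 12, the 10 genes with the highest mean TPM, the 5 genes with the largest differences in each direction among those with a mean of at least 100 counts, and the 3 beta and 3 alpha T cell receptor V segments with the highest mean TPM. Genes named outside that rule are marked as chosen after their values were seen. Some genes covered by the rule are not reported here.

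The alternative settings chosen then were DESeq2 size factors (1.07 and 0.933), total counts, count filters of at least 1 and at least 100, posterior mean counts, the older counts, edgeR's exactTest at an assumed dispersion of 0.01, TPM thresholds of 0.5 and 5, the lower credibility bound of TPM, FPKM in place of TPM, pseudocounts of 0.1, and each library alone. Removal of running-median trends of the log2 ratio with GC content, with length, with both and with local GC content was added after seeing the data. Local GC content was the GC content of the most GC-rich 100-base window, moved in steps of 10 bases, of the transcript that led the gene's TPM. GC content was computed from the transcript sequences of the annotation, and 86 genes had no sequence there. The property was reached after trying several others on genes with at least 500 counts, among them whole-transcript GC content, length, GC content of the transcript ends, base runs, CpG content, short words and other window sizes.

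The tests were tested on simulated libraries drawn from the real genes' totals and library sizes (16550 genes). Of genes changed 1.5-fold 58% were called, of genes changed 2-fold 67% were called, and 9 unchanged genes were called. The chi-square per degree of freedom was 1.02 for unchanged genes. The simulated counts held counting error alone, while the real libraries had a chi-square of 29.9. These rates therefore do not tell how the tests act under the spread between the real libraries. A simulated GC trend alone gave 6277 calls before its removal and 9 after it. Tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.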

Results

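The transcriptome of mouse regulatory T cells was profiled in 2 technical replicate libraries of 1 biological replicate, with 20891069 and 18571065 expected counts in genes. The profile was that of a Foxp3-expressing T cell population: all 20 genes of a list of regulatory T cell identity genes were detected, and Trbc2, a constant segment of the T cell receptor, had a TPM (transcript abundance scaled for length and depth) of 4083. A total of 12980 genes had a TPM of at least 1 in both libraries. Of these, 10472 were protein coding and 581 were processed pseudogenes, whose reads can be shared with their parent genes. Protein-coding genes took 93.4% of counts in technical replicate 1 and 93.9% in technical replicate 2, and ribosomal RNA genes took 1.23% and 1.26%. Across 14751 genes with a TPM of at least 1 in either library, log2(TPM + 1) had a Pearson r of 0.965 and TPM a Spearman rho of 0.963. These correlations are across genes, which are not independent replicates. As the labels gave a single group, levels are described first and the libraries are then compared with each other.

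Foxp3, the transcription factor that defines regulatory T cells (ENSMUSG00000039521.13, chromosome X, 7573644 to 7595245, mm10), had a mean TPM of 86.1 ± 3.55 (SD, n = 2 technical libraries) from 2034 and 1602 expected counts. Among the Treg identity genes, Il2rb, the beta chain of the interleukin-2 receptor, was the most abundant at 955 ± 23.2 TPM. It was followed by Izumo1r, the folate receptor 4 gene, at 788 ± 26.6 TPM and by the tumour necrosis factor receptor family genes Tnfrsf4 at 762 ± 3.54 TPM and Tnfrsf18 at 667.5 ± 69.0 TPM. Il2ra, the alpha chain of the interleukin-2 receptor, had 320.1 ± 7.30 TPM. Ctla4, an inhibitory receptor, had 269 ± 3.41 TPM and Ikzf2, which encodes the transcription factor Helios, had 252 ± 9.90 TPM. Nrp1, a receptor often found on thymus-derived regulatory T cells, had 211 ± 27.1 TPM. In the list as a whole the median of the mean TPM was 199, 14 genes reached 100 TPM and 18 reached 10 TPM. The least abundant members were Plagl1 at 7.01 ± 0.318 TPM and Dusp4, a phosphatase, at 5.6 ± 3.2 TPM.

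**Figure D1:**
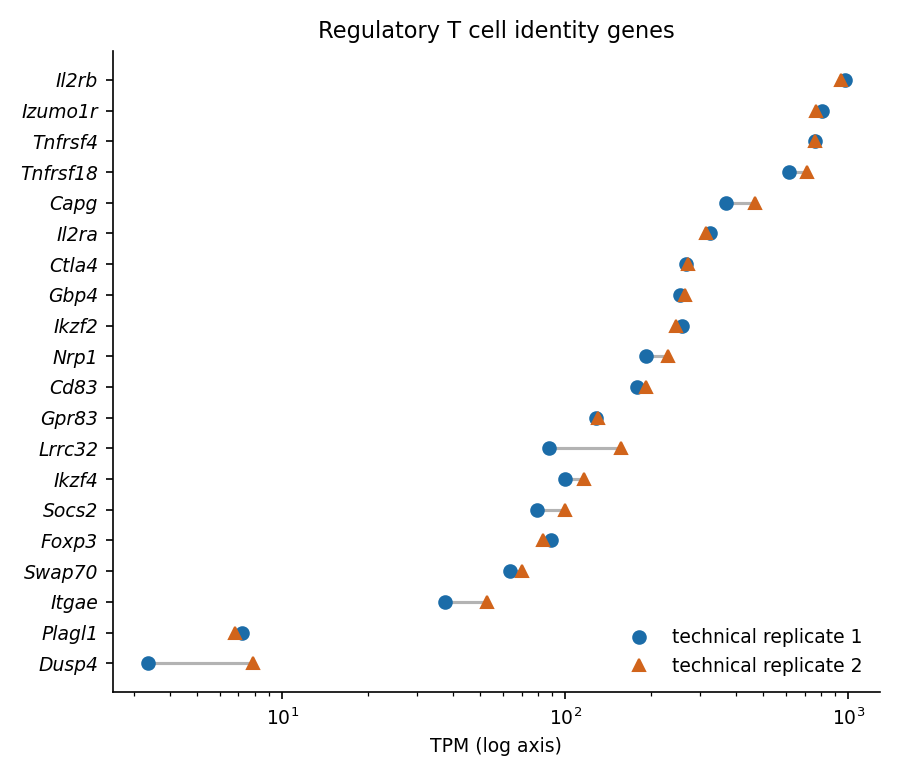
TPM (log axis) of the 20 Treg identity genes in each technical library, with circles for technical replicate 1, triangles for technical replicate 2 and a grey line joining them. Il2rb lies highest at a mean of 955 TPM and Dusp4 lowest at 5.6 TPM. Dusp4 is furthest apart between libraries on this axis, at 3.34 TPM in technical replicate 1 and 7.86 TPM in technical replicate 2. Lrrc32 follows, at 87.8 and 157 TPM.

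All 23 genes of a list of effector regulatory T cell genes were detected, with a median of 49.2 TPM and 7 genes at 100 TPM or more. The most abundant were Tnfrsf1b, a tumour necrosis factor receptor, at 269.7 ± 12.7 TPM, Tnfrsf9 at 221 ± 10.9 TPM, S100a4 at 208 ± 51.8 TPM and Icos, a costimulatory receptor, at 202 ± 0.7 TPM. Of 14 suppressive mediators, 13 were detected. Lgals1, which encodes galectin-1, had 437 ± 91.7 TPM, Nt5e, which encodes the ectonucleotidase CD73, had 177 ± 10.9 TPM, and Penk, the precursor of enkephalin peptides, had 168 ± 17.2 TPM. All 15 genes of a resting or central T cell list were detected at a median of 218 TPM. Ccr7, a chemokine receptor of lymph node homing, had 479.99 ± 43.0 TPM, Foxp1 had 353 ± 3.87 TPM and S1pr1, a receptor for exit from lymph nodes, had 332 ± 21.7 TPM. Genes of resting and of effector cells were thus present in the same bulk profile, which does not tell whether the same cells held both.

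All 20 genes of the T cell receptor complex and its proximal signalling were detected at a median of 657 TPM. The constant segments Trbc2, Trac and Trbc1 had 4083 ± 127, 2780.5 ± 337 and 2128 ± 99.3 TPM, and the kinase Lck had 1342 ± 39.9 TPM. Of the variable segments, 21 of 22 beta (Trbv) and 96 of 108 alpha (Trav) segments were detected. The beta segments with the highest mean TPM were Trbv13-2 (chromosome 6, 41121396 to 41121832) at 398 and 318 TPM, Trbv3 at 299 and 278 TPM and Trbv16 at 213 and 211 TPM in technical replicates 1 and 2. Trbv13-2 made up 13.8% and 11.9% of the summed Trbv TPM, and of these 3 it alone differed between the libraries (adjusted p = 3.52e-08, exact binomial test). Its expected counts, 1633.58 and 1107.01, were not whole, so some of its reads were shared with other genes. Trbv3 had more counts, at 1712 and 1349. The alpha segments with the highest means were Trav7d-2 at 86.3 and 69.1 TPM, Trav9-1 at 64.0 and 56.7 TPM and Trav14n-3 at 48.2 and 58.0 TPM. Many alpha segments are near-identical copies, so that their reads can be divided between them and single alpha values are uncertain. Between libraries, TPM of segments above 0 had a Spearman rho of 0.981 over 22 beta segments and 0.838 over 104 alpha segments.

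Of 16 effector genes of conventional helper T cells, 10 were detected, at a median of 3.86 TPM over the list. The highest were Cxcr5, the follicular homing receptor, at 69.8 ± 7.92 TPM, Cd40lg, a ligand of B cell help, at 62.7 ± 10.3 TPM, the cytokine gene Tnf at 47.5 ± 4.14 TPM and Bcl6, the transcription factor of follicular helper cells, at 17.5 ± 4.50 TPM. In technical replicates 1 and 2, Foxp3 had 28.8 and 13.5 times the TPM of Tbx21, which encodes the T helper 1 factor T-bet. Foxp3 also had 53.4 and 51.0 times the TPM of Il2, the cytokine that regulatory T cells respond to and mostly do not make. These 2 ratios were not part of the rule for named genes.

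Of 24 genes of cytokine receptors and JAK-STAT signalling, 23 were detected at a median of 163 TPM. Il2rg, the common cytokine receptor chain, had 1339.6 ± 1.85 TPM, the kinase gene Jak1 had 379 ± 168 TPM and Ifngr1 had 359 ± 27.0 TPM. All 25 genes of a list of transcription factors and chromatin regulators reported to act with Foxp3 were detected, led by Ets1 at 422 ± 114 TPM, Elf1 at 154 ± 8.85 TPM, Nfatc1 at 147 ± 15.3 TPM and Rela at 137 ± 6.17 TPM. All 11 genes of the TGF-beta pathway, which takes part in regulatory T cell development, were detected, with the receptor gene Tgfbr2 at 108 ± 50.1 TPM, Smad2 at 49.995 ± 3.53 TPM and Tgfbr1 at 48.0 ± 11.5 TPM. Of 16 chemokine receptor and homing genes, 15 were detected, and the highest were Selplg at 842 ± 79.2 TPM and the integrin genes Itgb7 at 742 ± 309 TPM, Itgal at 315 ± 18.2 TPM and Itga4 at 205 ± 6.82 TPM.

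All 14 cell cycle genes were detected, at a median of 10.6 TPM, and the replication factor Pcna had 142 ± 13.0 TPM, Mcm2 60.01 ± 1.91 TPM, Mcm5 45.3 ± 0.714 TPM and Tyms 32.9 ± 1.29 TPM. All 12 interferon response genes were detected, with Ifi27l2a at 1527 ± 33.7 TPM, Irf9 at 193 ± 2.85 TPM, Bst2 at 139 ± 0.438 TPM and Irf7 at 135 ± 8.90 TPM. All 11 genes of apoptosis and survival were detected, from Casp8 at 239 ± 6.34 TPM to Bak1 at 1.86 ± 0.0141 TPM. All 14 glycolysis genes were detected at a median of 158 TPM, with Ldha at 1041 ± 1.43 TPM, Eno1 at 980.2 ± 35.5 TPM, Pkm at 755 ± 10.6 TPM and Aldoa at 494 ± 14.6 TPM. All 13 protein genes of the mitochondrial genome were detected at a median of 1280.1 TPM. Genes of the mitochondrial chromosome took 2.15% of counts in technical replicate 1 (95% exact binomial interval 2.148% to 2.161%) and 1.55% in technical replicate 2 (1.543% to 1.554%). Of 16 immediate early and stress genes, 13 were detected, with Junb at 407 ± 189 TPM, Zfp36 at 225 ± 11.1 TPM, Ier2 at 149 ± 85.2 TPM and Nr4a1, which is induced by T cell receptor signals, at 101 ± 10.3 TPM. Of 10 replication-dependent histone genes, most of whose mRNAs carry no poly(A) tail, 6 were detected at low levels, the highest being Hist1h4d at 31.2 ± 3.03 TPM and Hist1h1c at 11.1 ± 2.84 TPM.

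Of the 10 genes with the highest mean TPM, 9 are given here: Tmsb4x, which encodes thymosin beta 4, at 14161 TPM, the ribosomal RNA gene CT010467.1 at 10672 TPM, the class I histocompatibility gene H2-K1 at 10649 TPM, B2m at 6146 TPM, the TEC-class transcript Gm37376 at 5496 TPM, mt-Co3 at 5223 TPM, the mitochondrial tRNA gene mt-Ts1 at 5075 TPM, Rps19 at 4999 TPM and H2-D1 at 4776 TPM. The value of mt-Ts1 rested on a length of 69 bases and on 1784 and 917 counts. Reads of the H2 genes, of the ribosomal protein gene Rps19 and of CT010467.1 can be shared with close copies, so that these values are uncertain. Gm37376 had 33420.2 expected counts in technical replicate 1, which are not whole. Some of its reads were thus divided with other genes, and its value is uncertain as well. The 10 genes with most counts together took 5.67% and 5.36% of counts.

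Markers of other cell types were mostly low. Over 12 lists, 32 of 79 markers were detected and 14 reached a mean of 10 TPM. No neutrophil marker was detected among 7, and 1 of 2 CD8 T cell markers was detected, with Cd8b1 at 24.1 ± 1.93 TPM and Cd8a at 0.685 ± 0.0354 TPM. The gamma-delta T cell list had 3 of 4 detected, the highest being Tcrg-C1 at 14.2 ± 2.62 TPM. Natural killer cell markers had 2 of 7 detected, with Klrb1c at 5.12 ± 1.77 TPM. The plasma cell list had 1 of 5 detected, which was Jchain at 1.85 ± 0.509 TPM, and the platelet or megakaryocyte list had 1 of 4, which was Itga2b at 1.30 ± 0.410 TPM. Monocyte or macrophage markers had 5 of 10 detected, with Lyz2 at 8.66 ± 2.43 TPM and C1qb at 7.62 ± 0.884 TPM. Dendritic cell markers had 5 of 10, of which Cd74, the invariant chain, stood at 176 ± 7.34 TPM while its class II partners H2-Ab1 and H2-Aa had 13.4 ± 3.39 and 9.88 ± 3.32 TPM. Erythroid markers had 5 of 6, with the globin genes Hbb-bs at 73.1 ± 9.05 TPM and Hba-a2 at 69.7 ± 5.53 TPM.

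The remaining marker lists each held a gene far above the rest of the list. Of 8 stromal, endothelial or epithelial markers 2 were detected, and Pecam1, which some leukocytes also express, had 119.6 ± 0.7 TPM against 2.02 ± 1.04 TPM for Epcam. Of 5 markers of double-positive thymocytes 2 were detected, and Cd1d1, which other blood cells also express, had 137 ± 1.67 TPM, while Rag1 and Rag2, the recombinase genes, were at 0 counts. Of 11 B cell markers 5 were detected, and Ighm, the constant region of the immunoglobulin mu heavy chain (chromosome 12, 113418558 to 113422730), ranked 105 of all genes at 1133 ± 13.4 TPM. The next B cell markers were Igkc at 42.7 ± 16.8 TPM, Cd79b at 32.6 ± 0.184 TPM, Ighd at 12.7 ± 2.25 TPM and Cd79a at 6.09 ± 0.283 TPM. Heavy chain V segments summed to 18.3 and 12.5 TPM, and 0 of 113 were detected.

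**Figure D2:**
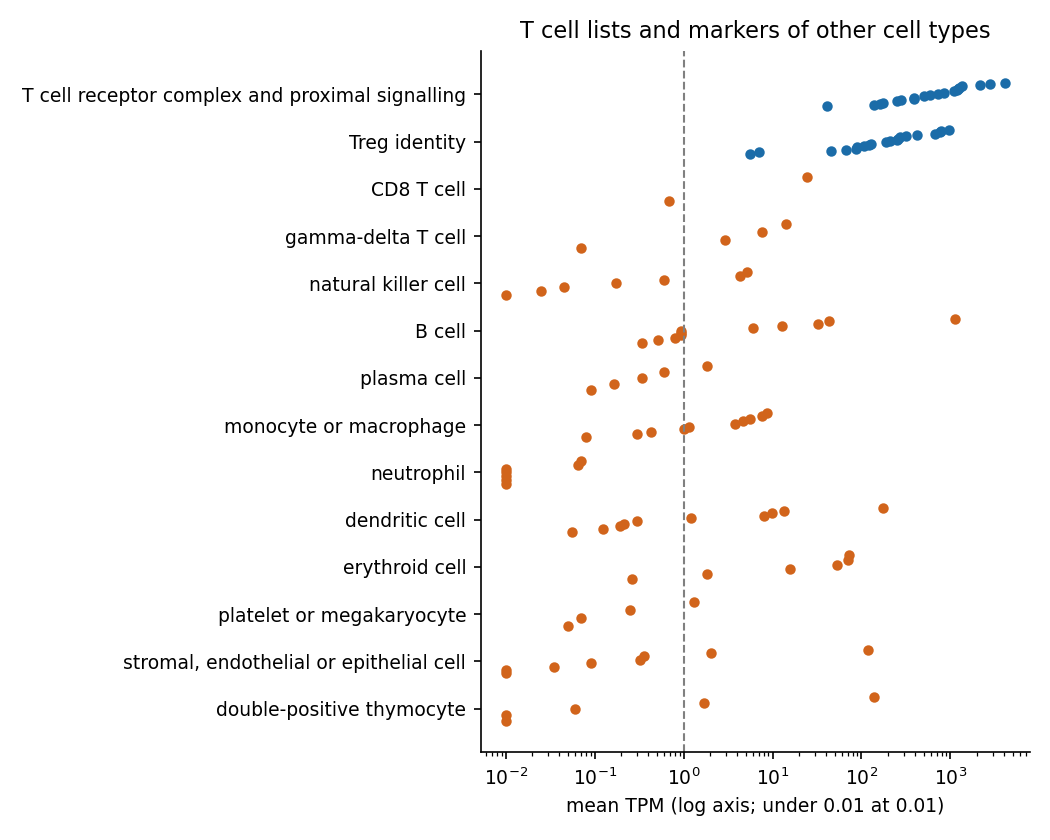
Mean TPM (log axis, values under 0.01 drawn at 0.01) of each measured gene of the T cell receptor and Treg identity lists (blue) and of the 12 marker lists of other cell types (orange), with a dashed line at 1 TPM. The B cell gene at the far right is Ighm at 1133 TPM.

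The sex-linked genes were those of a male: Eif2s3y, Ddx3y, Kdm5d and Uty had 102, 86.9, 40.7 and 37.0 TPM, and Xist, the RNA of the inactive X chromosome, had 0.01 TPM in each library. At the loci altered in the strain, Cd4 had 248 ± 0.792 TPM, the noncoding transcript Gt(ROSA)26Sor 43.5 and 20.6 TPM, and Hbegf, the mouse counterpart of the diphtheria toxin receptor, 2.33 ± 0.0919 TPM.

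The libraries were next compared with each other, which asks how far technical replicates of this profile differ. They were not the same library deposited again: 5640 of 16553 genes differed at an adjusted p under 0.05 (exact binomial test, Benjamini-Hochberg), of which 3536 were higher and 2104 lower in technical replicate 2, and 1016 differed at least 2-fold. Higher genes made up 62.7% of these calls, against 54.4% of 5967 calls with DESeq2 size factors, 48.1% of 6346 calls with total counts and 71.6% of 3058 calls in the older counts, so that the balance of directions depends on the scaling. The median log2 ratio over tested genes was 0.02 with TMM, −0.02 with DESeq2 size factors and −0.05 with total counts. The chi-square per degree of freedom was 29.9 (bootstrap 95% interval 27.6 to 32.8). Its median over genes was 2.57, where 0.455 would follow from sampling noise alone. Beyond counting error, the coefficient of variation was 19.4% over 9908 genes with a mean of at least 100 counts. With an assumed dispersion of 0.01 in edgeR's exactTest, 1784 genes differed, 86.2% of them higher in technical replicate 2. That dispersion stands for a coefficient of variation of 0.1, below the measured 0.194. These calls thus do not allow for all of the spread seen between the libraries.

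The immediate early and stress genes were mostly higher in technical replicate 2. Of 15 tested, 9 were higher and 3 lower over all genes tested, under all 3 scalings, and 13 differed when adjusted over the list alone. Junb went from 273 to 541 TPM (log2 ratio 0.98 ± 0.02, counting SE) and Ier2 from 89.0 to 209.5 TPM (1.23 ± 0.04, adjusted p = 1.07e-207, exact binomial test), while Zfp36 was lower (log2 ratio −0.10). The median log2 ratio of the list, 0.59, lay at percentile 99.99 of matched random lists. With the trend of local GC content removed, the median was 0.21 and the percentile 99.08.

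The protein genes of the mitochondrial genome were lower in technical replicate 2. All 3 scalings gave 12 of 13 lower and 0 higher, and 12 differed when adjusted over the list alone. The values for mt-Co3 were 6257 and 4189.6 TPM (log2 ratio −0.58) and for mt-Atp6 5021 and 2935 TPM (−0.78), and the median log2 ratio was −0.32, at percentile 0 of matched random lists. This direction was not kept by every setting: with the GC trend removed 3 were higher and 5 lower and the median lay at percentile 98.2. With the local GC trend removed 2 were higher and 8 lower, at percentile 4.92, within the central 95%.

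Of 24 cytokine receptor and JAK-STAT genes 17 were higher and 1 lower (19 differing when adjusted over the list alone), with Jak1 at 259.8 and 498 TPM. Of 25 Foxp3-associated factors 17 were higher and 2 lower (19 over the list alone), with Ets1 at 341 and 503 TPM, and of 11 TGF-beta pathway genes 6 were higher and 1 lower (7 over the list alone), with Tgfbr2 at 72.2 and 143 TPM. Of 16 chemokine receptor and homing genes 10 were higher and 3 lower (13 over the list alone), with Itgb7 at 523 and 961 TPM. Higher calls outnumbered lower calls in these 4 lists under all 3 scalings. With the local GC trend removed, the Foxp3-associated factors had 11 higher and 8 lower and the TGF-beta list 4 and 3. The TGF-beta median lay at percentile 86.8 of matched random lists, and at 70.04 with that trend removed, within the central 95%. The median of the Foxp3-associated factors went from percentile 99.28 to 97.03 on its removal, which is within the central 95% as well. The JAK-STAT list went from 99.92 to 99.62 and the chemokine list from 97.55 to 99.98, both outside the central 95% either way. The histone list went from 96.79, within it, to 98.33, outside it. The interferon list stayed within it, at 71.45 and 92.69. Histone genes had 5 higher and 0 lower of 9 tested (5 over the list alone), and interferon response genes 4 higher and 0 lower of 12 (4 over the list alone). Total counts gave 3 higher and 1 lower for the interferon list.

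The Treg identity list had 10 of 20 genes higher and 4 lower with TMM (15 differing when adjusted over the list alone), but 8 higher and 7 lower with either other scaling. It had 12 higher and 1 lower with the local GC trend removed. Its median log2 ratio of TPM + 1 was 0.080, at percentile 99.02 of matched random lists. With the local GC trend removed it was 0.093, at 99.7. The median log2 ratio of counts was 0.048 with TMM, 0.013 with DESeq2 size factors and −0.016 with total counts, so the shift was small and its direction depends on the scaling. With TMM Foxp3 did not differ at 88.6 and 83.6 TPM (log2 ratio −0.11 ± 0.05, adjusted p = 0.0626, exact binomial test), although DESeq2 size factors gave 0.00928 and total counts 0.00123. Its log2 ratio passed the test at −0.28 with the GC trend removed (adjusted p = 3.62e-08), −0.25 with the GC and length trends removed and −0.13 with the length trend removed, but not with the local GC trend removed (−0.09, adjusted p = 0.166). Whether Foxp3 differed thus depends on the setting. Lrrc32, which encodes the TGF-beta docking receptor GARP, differed at a log2 ratio of 0.92 ± 0.03, and Dusp4, at 3.34 and 7.86 TPM, at 1.23 ± 0.16. Of 23 effector regulatory T cell genes 12 were higher and 6 lower (19 over the list alone), which total counts turned to 8 and 9. The median of this list lay at percentile 98.8, but at 88.9 with the local GC trend removed, within the central 95%. Suppressive mediators had 4 higher and 3 lower of 13 tested (8 over the list alone), and both other scalings gave 3 and 4. Resting T cell genes had 6 higher and 5 lower of 15 (11 over the list alone), against 5 and 6 with DESeq2 size factors and 5 and 8 with total counts.

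Of 20 T cell receptor genes 13 were lower and 3 higher with TMM (16 when adjusted over the list alone), among them Trac at 3019 and 2542 TPM. With the local GC trend removed 10 were lower and 5 higher, while the older counts gave 0 lower and 4 higher. Densely read genes such as Trac kept few of their reads in the older table, so whether this turn in direction is real was left open. The median log2 ratio of this list was −0.08, at percentile 29.0 of matched random lists. Conventional helper genes had 5 of 10 lower and 3 higher (8 over the list alone), a split of 5 and 2 with both other scalings, with Bcl6 at 20.7 and 14.3 TPM and a list median of −0.26 at percentile 0.190. Glycolysis genes had 5 lower and 2 higher of 14 (8 over the list alone), cell cycle genes 1 lower and 2 higher of 14 (3 over the list alone), and apoptosis and survival genes 2 lower and 3 higher of 11 (5 over the list alone). For glycolysis genes DESeq2 size factors gave 7 lower and 2 higher and total counts 9 and 1. For cell cycle genes the other scalings gave 2 lower and 2 higher, and for apoptosis genes total counts gave 4 lower and 3 higher. Sex-linked genes had 2 of 4 lower (2 over the list alone), 3 with total counts, but 0 lower and 2 higher with the GC trend removed. Of the engineered loci Gt(ROSA)26Sor alone was lower with TMM, at a log2 ratio of −1.16 ± 0.11 (2 of 4 over the list alone). DESeq2 size factors gave 2 lower engineered loci and total counts 3. Among marker lists the calls over all genes tested were 2 of 8 dendritic cell, 2 of 9 monocyte or macrophage, 1 of 3 natural killer and 1 of 11 B cell genes lower, 1 of 4 stromal genes higher, and 2 higher and 1 lower of 6 erythroid genes. Adjusted over the list alone, those counts were 2, 2, 1, 1, 1 and 3. Total counts gave 4 of 8 dendritic cell and 4 of 11 B cell genes lower. The CD8, gamma-delta, plasma cell, platelet and thymocyte lists had 0 calls either way with TMM.

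An assumed dispersion of 0.01, which allows for some spread beyond counting but less than was measured, left fewer list calls. The JAK-STAT list and the Foxp3-associated factors each had 5 higher and 0 lower, the chemokine list 4 and 1, the histone list 3 and 0, and the TGF-beta, Treg identity and effector lists 2 and 0 each. The immediate early list had 7 higher and 0 lower and the mitochondrial list 0 higher and 3 lower. The T cell receptor, interferon, glycolysis, cell cycle and resting T cell lists had 0 calls.

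Over all lists, 9 of 26 with at least 3 tested members had a median outside the central 95% of matched random lists. Genes with a high local GC content made up much of the excess of higher genes, a relation that was looked for after the data were seen. Of 2550 genes whose most GC-rich 100-base window had over 75% to 85% GC, 42.1% had a log2 ratio above 0.6, against 4.04% of 6139 genes at 70% or less. The share was 14.4% at over 85%. In all, 1574 genes of 11155 with at least 100 counts lay above 0.6 and 215 below −0.6. Spearman's rho with the log2 ratio was 0.439 for local GC content and 0.299 for whole-transcript GC content across these genes.

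**Figure D3:**
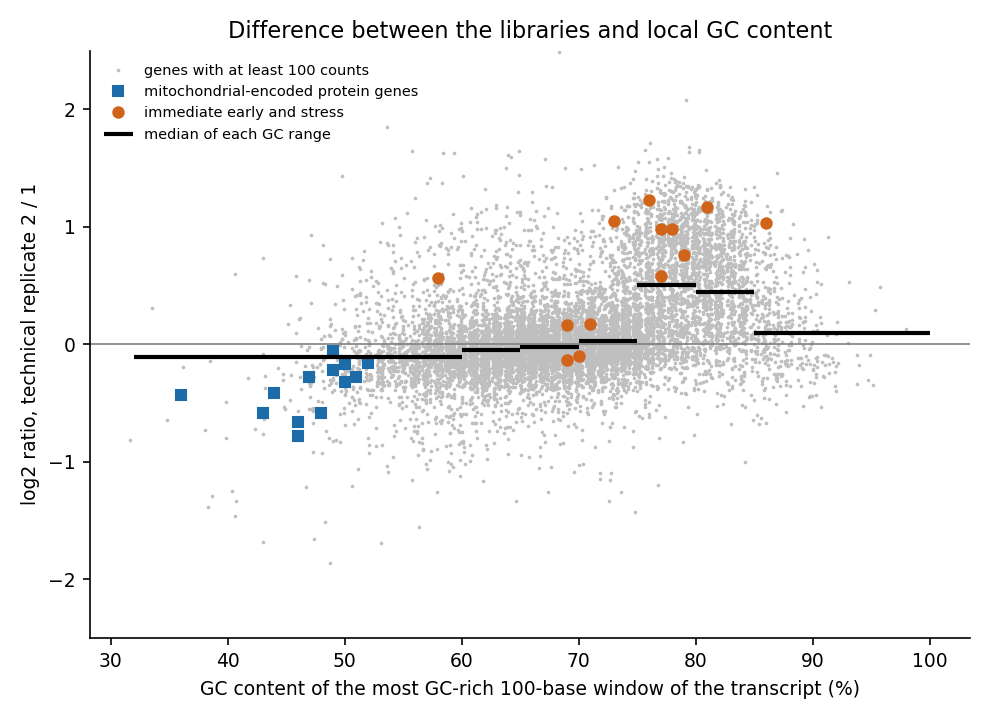
Log2 ratio of technical replicate 2 to 1 against the GC content of the most GC-rich 100-base window of the leading transcript, for 11155 genes with at least 100 counts (grey; 20 lie beyond the axis). Black lines are the medians of GC ranges, which reach 0.51 between 75% and 80%; orange points are immediate early and stress genes and blue squares are mitochondrial protein genes.

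Among the 5 genes with the largest ratios in each direction were several pseudogenes or members of multigene families, for which the division of shared reads is uncertain: Gm9923, Ppp1ccb and Gm15387 were higher and Gm6361, Xlr3b and Gm2981 lower in technical replicate 2. The protein-coding gene Gm38431 was also lower, at 254 and 29.8 counts. Its log2 ratio was −2.83 with expected counts but −1.17 with posterior mean counts. Gm9923 had 0 and 293 counts, Gm6361 had 212 and 0 counts, and no ratio is given for either. The small RNA gene Gm26377 (chromosome 9, 78478528 to 78478635), of 108 bases, had 783.74 and 61.32 counts. Neither count is whole, so some of its reads were shared with other genes and their division is uncertain here too. Rcn3, which encodes a calcium-binding protein of the endoplasmic reticulum (ENSMUSG00000019539.11, chromosome 7, 45082913 to 45092221, minus strand), had 133 and 1759.6 counts, a log2 ratio of 3.95 ± 0.13, and 47 and 904 counts in the older table. Sp6, a transcription factor gene (chromosome 11, 97013394 to 97024734), had 119 and 429 counts, a log2 ratio of 2.08 ± 0.15, and 66 and 155 older counts. With the local GC trend removed the log2 ratio was 1.46 for Sp6 and 3.96 for Rcn3.

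At the level of transcripts, the leading transcript was the same in both libraries for 18 of the 20 Treg identity genes, of which 1 has a single annotated transcript. The exceptions were Tnfrsf18 and Socs2. Foxp3 was led by ENSMUST00000234479.1, a transcript of 1557 bases, at 50.1% and 53.6% of the gene. Il2ra was led by a transcript of 4412 bases at 72.5% and 71.1%, and Ctla4 by a transcript of 1933 bases at 98.9% and 99.1%. For Tnfrsf18 the transcript of 1189 bases that led technical replicate 1 at 44.0% had 28.9% in technical replicate 2, where a transcript of 1078 bases led at 43.7%. For Socs2 the leader went from a transcript of 2222 bases at 32.9% to a transcript of 948 bases at 41.0%.

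The older and newer gene tables of the same library ranked genes differently in part. Over genes with at least 10 expected counts, Spearman's rho between the tables was 0.884 in technical replicate 1 (11819 genes) and 0.886 in technical replicate 2 (11648 genes). After median scaling, 1118 and 1037 genes were over 4-fold apart, of which 1082 and 1001 were lower in the older table. Tmsb4x, the gene with the highest mean TPM, had 132893 expected counts and 539 older counts in technical replicate 1. The ratio of older to expected counts had a median of 0.491 over 8258 genes under 1 expected read per exonic base and 0.0185 over 57 genes at 10 or more. No gene exceeded 2 older counts per exonic base, the highest being 1.94.

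**Figure D4:**
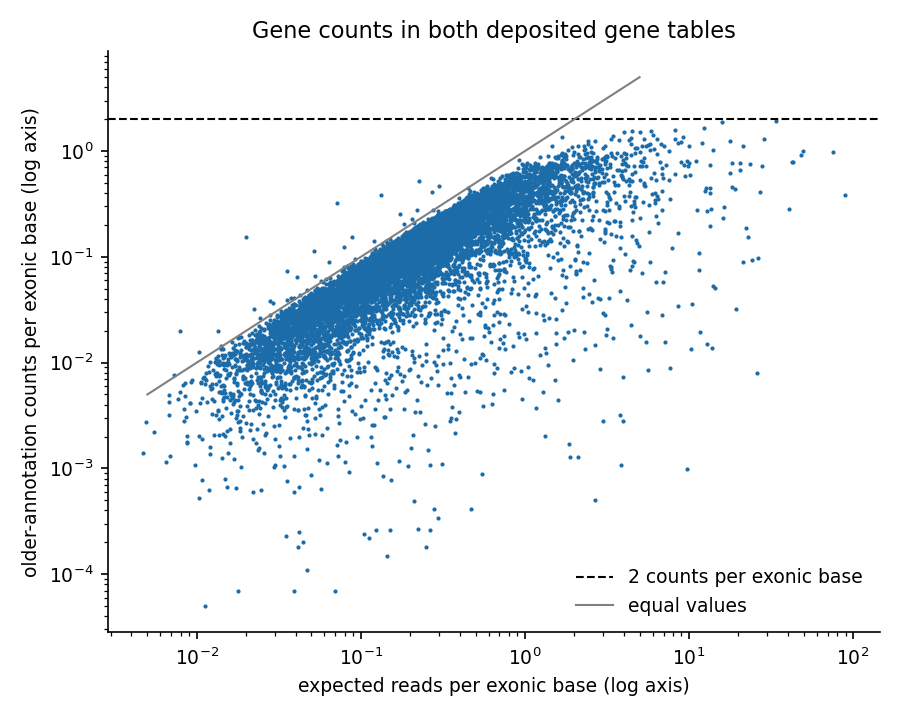
Older-annotation counts against expected counts, both per exonic base and on log axes, for 9164 genes drawn as points. The grey line marks equal values and the dashed line 2 older counts per base, which no gene exceeds.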

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

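Of the tests in this part, those of PCR copies, of GC content and length together and of the older counts were chosen only after the result was seen. The test of the immediate early list was set before its value was computed but after the list's shift had been seen, and local GC content was reached after several other sequence properties had been tried.

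Rows outside the genes held signal above the limit of 3 counts. The phiX174 row, the genome of a phage commonly added to sequencing runs, held 62467 counts in technical replicate 1 and 43472 in technical replicate 2. The rows with numeric identifiers held 1949.24 and 1500.89 counts.

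The first pattern is that the technical libraries differed by more than sampling noise. The chi-square per degree of freedom already allows for unequal depth through the scaled library sizes, and was 1.02 in simulated libraries of these depths with counting error alone. It stayed at 27.6 after thinning the deeper library. Because of that scaling, thinning could hardly have removed the excess and is no separate test of depth. The chi-square stayed at 23.1 after removal of the GC and length trends together. Such a removal takes out only the median shift that genes of like GC content or length share. The median trends were thus not the whole cause, but the test cannot exclude GC content and length themselves. GC content alone (rho 0.299, 5468 genes still differing) and length alone (rho 0.205, 5591 genes) met only part of what each required and stay open as partial causes. A GC-rich stretch in the transcript is a candidate explanation for part of the pattern. It was tested among genes with at least 100 and under 500 counts, left aside when the property was found in these libraries. Their share above a log2 ratio of 0.6 was 6.05 times higher at local GC over 75% to 85% than at 70% or less. In these genes rho was 0.349 for local and 0.320 for whole-transcript GC content, so the test does not tell a GC-rich stretch from GC content as a whole. Removing the local GC trend left the chi-square at 20.7. That removal too takes out only a shared median shift, so it cannot decide whether GC-rich stretches are the whole cause. An immediate early response in the cells of technical replicate 2 and a leftover of the library bias cannot be told apart, because the list stayed at percentile 99.08 and the labels do not say whether the cells were handled separately. Copies of a fragment made by PCR also stay open, since extra variation was 18.1% in the older counts against 19.3% in expected counts of the same 6830 genes, and whether the older counts take reads at a position once is not settled.

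The second pattern is that the older counts were lower than the expected counts, most of all in densely read genes. If reads at the same position were counted once, the ratio would fall with read density; rho was −0.25 over 9246 genes, short of the −0.5 required, so this stays open, though the highest value was 1.94 counts per exonic base. For counting of uniquely mapping reads only, the ratio had to show little dependence on density, a rho above −0.2, among genes whose reads are assigned without ambiguity, and rho was −0.18 over 4978 genes with whole expected counts. A later test went against it for dense genes: 15 genes with whole expected counts and at least 10 reads per base had a median ratio of 0.0331, against 0.512 in 4548 sparsely read genes. No biological explanation was tested, as both tables come from the same libraries.

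The third pattern is the abundance of Ighm beside low levels of other B cell markers. B cells as its source were excluded, since heavy chain V segments, part of each rearranged heavy chain mRNA, summed to at most 1.58% of the TPM of Ighm and Ighd, while T cell receptor V segments reached 50.3% and 50.9% of their constant segments (beta alone 45.4% and 44.3%). Unrearranged transcription of the heavy chain constant region may account for the level. Its prediction of a low share was met, with 1.10% in the lower of the libraries. That is the same measure that was used against B cells, so it adds no separate support. Unrearranged transcription is a hypothesis, and reads of hypermutated V segments that failed to align were not examined. A small number of B cells remains possible, since kappa V segments had 47.3% and 43.3% of the TPM of Igkc, which ran at 54.5 and 30.8 TPM.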

How the results depend on the processing

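The settings that removed a trend were chosen only after the data were seen; the others were planned. Counts of detected genes (9372 to 14658), of detected Treg identity genes (19 or 20), of lists outside the central 95% (8 to 11) and of genes with the same leading transcript (18) stayed within 1.5 times of the reported value under their alternatives. Taken alone, technical replicate 1 had 13838 genes detected and technical replicate 2 had 13893. Of 16553 genes tested, 1784 differed with an assumed dispersion of 0.01, which allows for more spread by construction, and 3058 of 11507 differed in the older counts, which are fewer. The chi-square per degree of freedom was 43.1 at 100 counts or more, 18.0 at 1 count or more, 20.9 without the 100 genes of largest chi-square, 25.4 with the GC trend removed, 27.1 with the length trend, 23.1 with both and 20.7 with the local GC trend. Pearson's r was 0.909 at a pseudocount of 0.1, 0.982 with no filter and 0.967 with FPKM. At a TPM of at least 5, 21 markers of other cell types were detected. The gene tables had a mean rho of 0.816 at 100 counts or more, and a mean of 2493.5 genes were over 2-fold apart. Over all alternatives, log2 ratios of the Treg identity and other named genes kept their direction but lost their call 36 times and gained a call 14 times; others turned direction. In the older counts these were Ikzf2 at 0.14, Tnfrsf4 at 0.080, Il2ra at 0.027, Il2rb at 0.099, Izumo1r at 0.091, Gbp4 at 0.0074, Tmsb4x at 0.070 and B2m at 0.086. Densely read genes kept few of their reads in the older counts (539 and 523 for Tmsb4x, against 132893 and 110915 expected), which cannot test direction there. With the GC trend removed they were Ikzf2 at 0.25, Gpr83 at −0.034, Tnfrsf18 at −0.017, CT010467.1 at −0.0029, H2-K1 at −0.0500 and B2m at 0.0011. With the length trend removed Tmsb4x had 0.068, Ctla4 −0.0034, Tnfrsf4 0.050 and Gpr83 −0.089, and with both removed Ikzf2 had 0.16, Tnfrsf4 0.021, Gpr83 −0.12, Tmsb4x 0.13, B2m 0.12 and Gm37376 0.011. With the local GC trend removed Ikzf2 had 0.11, Tnfrsf4 0.028, Gpr83 −0.012, Il2ra 0.035 and CT010467.1 had −0.49. Ctla4, Gpr83 and H2-K1 had −0.011, −0.018 and −0.0081 with DESeq2 size factors and −0.040, −0.047 and −0.037 with total counts. Ctla4, Ikzf2, Tnfrsf4 and Gpr83 did not differ as reported. The cause of these turns was not tested. No paired analysis was possible because there was 1 group. Depth limits low genes: 3 counts of Foxp3 corresponded to 0.131 TPM in technical replicate 1.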

Other observations

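The comparisons in this part were all chosen only after the values were seen, and the genes named in it fall outside the rule for named genes unless they appear above. Single genes that stood out were picked by eye, with no list fixed for them and no enrichment test. Il21, a cytokine of follicular helper cells, had 5.96 and 1.25 TPM (log2 ratio −2.71 ± 0.27, adjusted p = 3.41e-34, exact binomial test), Il4 had 5.63 and 2.59 TPM (−1.08 ± 0.41), Pdcd1 had 169 and 127 TPM (−0.41 ± 0.03), Maf had 28.1 and 23.9 TPM (−0.33 ± 0.05) and Cxcr4 had 21.5 and 10.6 TPM (−1.02 ± 0.11). Cxcr5, Bcl6 and Cd40lg had log2 ratios of −0.23, −0.54 and −0.34, and Icos did not differ (−0.05, adjusted p = 0.126). Tbx21 went the other way, at 1.00 ± 0.18.

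Some genes of antigen-presenting and other cells were lower in technical replicate 2: Lyz2 at 10.4 and 6.94 TPM, H2-Aa at 12.2 and 7.53 TPM, H2-Ab1 at 15.8 and 11 TPM, Klrb1c at 6.38 and 3.87 TPM and Igkc at 54.5 and 30.8 TPM, all picked because they passed the test. Most markers did not: 2 of 8 dendritic cell, 2 of 9 monocyte or macrophage and 1 of 11 B cell genes were lower, against 2104 of all 16553 genes tested. Kappa V segments summed to 25.8 and 13.3 TPM. The medians of the helper, dendritic cell and monocyte or macrophage lists lay at percentiles 0.190, 0.560 and 3.24 of matched random lists, and at 2.29, 0.6 and 1.99 with the local GC trend removed. The B cell list lay at 24.7 and 50.4 and the erythroid list at 62.0 and 76.8. These 2 lists and, with no trend removed, the monocyte or macrophage list were within the central 95%.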
